A study of Saccharomyces cerevisiae and Schizosaccharomyces pombe with 8 samples.

How the data were processed

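The series measured the 3' ends of polyadenylated RNA in the budding yeast S. cerevisiae and the fission yeast S. pombe. It holds 8 libraries in 6 groups. S. cerevisiae wild type was grown in minimal and in rich medium, with 2 libraries per medium. S. pombe has 1 library each of wild type in rich medium, wild type in minimal medium, a PAB2 mutant in rich medium and a PCF11 mutant in minimal medium. The labels do not describe the mutations, the recipes of the media, or whether same-group libraries came from separate cultures.

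Per the labels' protocols, total RNA was used with a library method that amplifies the 3' ends of poly(A)+ RNA. Per the submitters' processing notes, reads were aligned with Bowtie2, with no version given, and the assembly is named as ASM294v2 for every library. ASM294v2 is an S. pombe assembly, so the notes do not name the assembly used for S. cerevisiae. The deposited values are counts: raw reads per chromosome, strand and cleavage position, with no normalization recorded by the authors and no header line. The coordinates were tested against the reference genomes, S. cerevisiae R64 and S. pombe ASM294v2. At positions with at least 20 reads, the next genomic base was A at no more than 0.646% of positions on any of the 16 S. cerevisiae chromosomes. That share lay between 0.523% and 0.954% on the 3 S. pombe chromosomes. Another base, 8 nt downstream, was A at 19.0% to 29.0% and 30.3% to 31.1% of positions. The positions were therefore read as 1-based coordinates of those assemblies, and all coordinates given are on them. The near absence of A after the cleavage position also means that the files had already been filtered or placed with respect to that base.

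Each read was assigned by strand to the coding or structured RNA gene from its start codon (structured genes, from their first base) to 500 nt past the annotated gene end. Long noncoding RNA genes took reads that no such gene held. A gene nested in another took the reads within its own bounds, and a downstream gene took reads from its start codon on. The S. cerevisiae annotation holds no UTRs, so its gene end is the stop codon, whereas the S. pombe genes end at the annotated transcript end. Reads on sequences other than the nuclear chromosomes were left out of all gene-level measures. Strand is given in the files, so antisense reads were counted apart. Near-identical gene copies, such as PHO12 with PHO11 or HXT6 with HXT7, can share reads, and how the aligner placed such reads is not stated.

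Cleavage positions within 24 nt of a gene's most used position were joined to it as a site, and the step was repeated on the positions left. Sites with at least 5% of the gene's reads over the libraries of the species were kept. For each gene the proximal and the distal of its 2 most used sites were compared. The S. pombe sites were ranked over all 4 S. pombe libraries, mutants included. A site used mainly in a mutant could thus be picked for that reason, and no ranking on wild type alone was made. For the number of sites per gene, each gene was thinned to 50 reads in each library, so that depth did not set the number. The S. cerevisiae site use test took genes with a mean of at least 20 reads per library over both sites. The read-weighted distance from the stop codon used reads downstream of the stop codon in genes with a mean of at least 20 reads per library.

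S. cerevisiae expression was tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM, filterByExpr) in R 4.3.3. Site use was tested with edgeR on the reads of both sites per library, with terms for library, site and the medium's effect on the distal over proximal ratio. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Log2 changes are minimal minus rich medium. The 19 S. cerevisiae gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2), and again with an estimated correlation. The position summary was tested with an exact two-sided permutation test, which cannot go below p = 0.333 with 2 libraries against 2. Apart from those of camera and of Fisher's exact tests, p-values measure only the spread between libraries, which may be technical. Camera set the changes of a list's genes against those of the other genes. Its p-values therefore rest on the spread across genes and on the correlation assumed between them. Fisher's exact tests compared counts of genes, taken as independent, so their p-values do not measure that spread. DESeq2 1.42.0 was used as an alternative.

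In S. pombe each group is 1 library, so no test across genes was made. Log2 ratios used reads plus 1 over TMM-scaled library sizes, in genes with at least 100 reads in the pair. A gene with few reads in one library could reach that minimum only through the other. Counts of list members past 2-fold therefore lean toward such genes. Site use was the log2 change of distal plus 1 over proximal plus 1 reads, in genes with at least 100 reads over both sites in the pair. A ratio of at least 2-fold was counted. For genes without reads in a library, ratios were taken against a floor of 3 counts in that library. Intervals are 95% exact Clopper-Pearson intervals for ratios and 95% Wilson intervals for shares. They cover counting error only, since reads without molecular identifiers are not independent molecules. The 17 S. pombe lists were described by the percentile of their median among 10000 random lists of the same size matched on mean expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

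Comparisons, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took the 8 largest rises and falls in S. cerevisiae expression (mean of at least 20 CPM, past the threshold, without overlap between media) and the 6 largest changes per direction in the other comparisons. It added up to 2 members per list with the largest change, every cleavage and polyadenylation factor where site use is given, and the PAB2 and PCF11 loci. Genes named beyond this rule, as further members of a list or in the closing part, were chosen after their values were seen. Not every gene that the rule takes is named in the text, and one item that it takes for S. cerevisiae site use is not reported here. The downstream GTA motif was added later, and no Fisher's exact test was part of that plan. Some list members do not do what the list's name says: the S. pombe list of cleavage and polyadenylation factors holds hrp1, a chromatin remodeller in that species, pab1, a protein phosphatase 2A subunit, with cph1 and cph2, and the Mmi1 list holds arg1. The S. pombe ribosomal protein list holds rpp40 and the S. cerevisiae list RPP1.

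The tests were run on simulated counts with 200 changed genes. In the S. cerevisiae expression test 58.5% of 2-fold and 95% of 4-fold changes were recovered over 4538 and 4542 genes, and in the site use test 15.5% and 63% over 2460 genes. Calls on unchanged genes numbered 2 and 8 for expression, and 1 and 11 for site use. The simulated S. cerevisiae counts used the same dispersion for every gene and both media. The rich medium replicates differed more than the minimal ones, so these numbers may not hold for the data. For the S. pombe expression ratio, all 200 of the 4-fold changes were recovered, and 0 of the unchanged genes among 3216 passed 2-fold. The simulated S. pombe counts held counting error alone, so that 0 does not cover the spread between libraries. Alternatives covered the scaling, the tool, filters, the reach past the gene end, the joining distance, minimum site use, pseudocounts, the replicate number as a block, and each S. cerevisiae library left out in turn. The 3 alternatives added after seeing the data were a region of 1 to 500 nt past the stop codon in both species, each library left out for the end position, and S. pombe reads within the annotated gene alone.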

Results

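Reads at 3' cleavage positions were counted in 4 S. cerevisiae and 4 S. pombe libraries. The S. cerevisiae libraries held 1174191 and 1253021 reads in minimal medium and 2057269 and 1558011 reads in rich medium. The S. pombe libraries held 3647664 reads for wild type in rich medium, 2702105 for wild type in minimal medium, 4488357 for the PAB2 mutant in rich medium and 3414864 for the PCF11 mutant in minimal medium. YHB1, the flavohemoglobin gene, took 11.2% to 13.0% of nuclear reads in each S. cerevisiae library. Among S. pombe genes rpl301, for a ribosomal protein, took the largest share of nuclear reads in 3 libraries (7.68% to 11.2%) and tdh1, for glyceraldehyde-3-phosphate dehydrogenase, in the PCF11 mutant library (9.04%). Replicates correlated across 4639 genes at r = 0.981 in minimal and 0.977 in rich medium, and libraries of different media at 0.920 to 0.927. These values are across genes, which are not independent replicates. Replicates differed by more than counting error, with a chi-square per degree of freedom of 2.42 in minimal and 9.60 in rich medium.

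The title of the series names a comparison of alternative polyadenylation in both yeasts. More genes used several sites in S. pombe wild type than in S. cerevisiae. At 50 reads per gene, 63.9% and 66.6% of S. cerevisiae genes in minimal medium and 68.2% and 67.3% in rich medium had at least 2 sites. In S. pombe wild type, the share was 80.1% of 3304 genes in rich medium (95% Wilson interval 78.7% to 81.4%) and 78.1% of 3011 genes in minimal medium (76.6% to 79.6%). It was 77.3% in the PAB2 mutant (75.9% to 78.7%) and 68.6% in the PCF11 mutant (66.7% to 70.4%). The lowest S. pombe wild-type library lay 9.98 percentage points above the highest S. cerevisiae library, and 5.94 points above it when only the stretch 1 to 500 nt past the stop codon was counted in both. With sites joined within 12 nt that distance was 3.41 points. Joined within 48 nt, 49.4% to 53.0% of genes in the S. cerevisiae libraries and 70.5% and 73.2% in S. pombe wild type had at least 2 sites. Over that 1 to 500 nt stretch, S. cerevisiae libraries lay between 63.7% and 64.2%, S. pombe wild type at 72.0% and 70.2%, the PAB2 mutant at 70.9% and the PCF11 mutant at 57.3%. The lower share of the PCF11 mutant depended on the reads per gene. At 20 reads it was 89.7%, against 89.2% in the PAB2 mutant, and at 200 reads 54.3% against 68.3%. At 20 reads a single read is 5% of the gene and counts as a site. The genes also differed, with 3546 at 20, 2442 at 50 and 1043 at 200 reads in the PCF11 mutant. The near-equal shares at 20 reads therefore cannot show that the mutants did not differ.

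The read-weighted 3' end of the median gene lay closer to the stop codon in S. cerevisiae than in S. pombe. In S. cerevisiae it lay 134.8 nt ± 0.738 (SD, n = 2) past the stop codon in minimal medium and 133.4 nt ± 0.665 (SD, n = 2) in rich medium, over 3597 genes. The difference of 1.40 nt had p = 0.333 in the exact two-sided permutation test, the smallest value that 2 against 2 libraries allow. Without minimal medium replicate 1 the difference was 0.875 nt, and with all reads of the gene it was 5.10 nt. In S. pombe, over 3910 genes, it lay at 187.5 nt in wild type in rich medium, 191.7 nt in wild type in minimal medium, 214.3 nt in the PAB2 mutant and 259.5 nt in the PCF11 mutant. With S. pombe reads limited to 500 nt past the stop codon, over 3519 genes, the values were 157.6, 162.1, 172.4 and 193.5 nt. With all reads of the gene, those upstream of the stop codon included, they were 127.0, 138.7, 184.8 and 169.3 nt over 4168 genes. The PAB2 mutant then lay furthest. It also had the lowest share of nuclear reads from start to stop codon (0.717%, against 1.13% in the PCF11 mutant and 1.82% and 1.76% in wild type in rich and minimal medium).

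The sequence elements around sites differed between the species. TAYRTA, the efficiency element of budding yeast, stood 20 to 80 nt upstream of 67.6% of the most used S. cerevisiae sites and of 16.3% of those in S. pombe. At background positions 200 nt downstream the shares were 10.7% and 14.2%, and at those 200 nt upstream 4.55% and 6.97%. Over all sites, 56.5% in S. cerevisiae and 15.8% in S. pombe carried TAYRTA. AATAAA stood 10 to 35 nt upstream of 17.7% of the most used S. pombe sites (downstream background 5.04%, upstream 1.83%) and of 7.31% in S. cerevisiae (3.25% and 2.39%). Over all sites the AATAAA shares were 13.5% and 6.73%. GTA within 30 nt downstream was found at 53.5% of the most used S. pombe sites (39.4% and 28.7%). It was found at 34.2% of the most used S. cerevisiae sites (31.3% and 31.6%). Over all sites the GTA shares were 49.9% in S. pombe and 35.6% in S. cerevisiae. Distal S. pombe sites carried GTA at 58.2% and proximal sites at 44.2%. In S. cerevisiae, 65.1% of proximal and 48.1% of distal sites carried TAYRTA.

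Reads fell mostly in the 3' region of coding genes. That share was 94.0% to 95.6% in S. cerevisiae and 94.7%, 94.5% and 92.4% in S. pombe wild type in rich medium, wild type in minimal medium and the PAB2 mutant. It was 83.5% in the PCF11 mutant. Antisense reads made up 0.748%, 0.724%, 1.29% and 5.52% of the same S. pombe libraries in that order, with a Wilson interval of 5.50% to 5.54% for the PCF11 mutant. Of these antisense reads, 39.2%, 41.0%, 43.9% and 45.7% lay within 2000 nt past a stop codon on their own strand, as did 38.5% of all S. pombe antisense positions. Structured RNA genes held 0.240%, 0.246%, 0.574% and 1.37% of reads, and long noncoding RNA genes 1.26%, 1.50%, 2.95% and 2.91%.

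**Figure D1:**
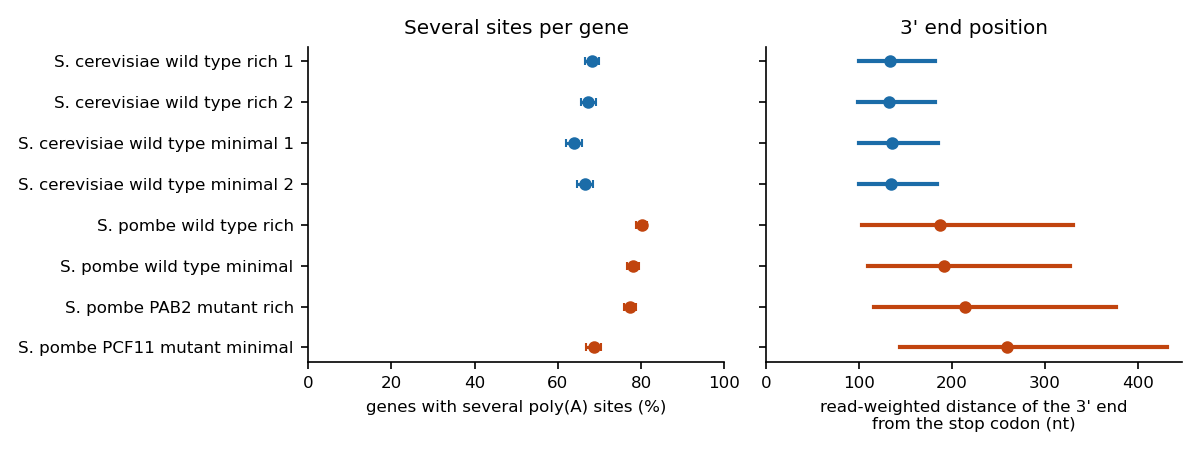
Left, percent of genes with at least 2 poly(A) sites in each of the 8 libraries, with 95% Wilson intervals; right, median and quartiles of the read-weighted 3' end position in nt past the stop codon. The PCF11 mutant has the lowest share of the S. pombe libraries (68.6%) and the most distant median end (259.5 nt).

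In S. cerevisiae, minimal against rich medium asks how the wild type differs when nutrients must be made. At the preset correlation camera called 8 of 19 gene lists up in minimal medium, led by amino acid biosynthesis, and 2 down, the phosphate response and iron and copper uptake, but with an estimated correlation it called 0. ZRT1, the high-affinity zinc transporter (chromosome VII, 20978 to 22108), rose from 67.1 ± 0.109 to 3669.7 ± 152 CPM (SD, n = 2), and PHO84, the high-affinity phosphate transporter (chromosome XIII, 24037 to 25800), fell from 418 ± 70.8 to 1.80 ± 2.54 CPM (SD, n = 2). Of 4639 genes tested, 818 rose and 729 fell, and 2005 had an unadjusted p under 0.05. DESeq2 called 484 and 360, without minimal medium replicate 1 the counts were 408 and 277, and without minimal medium replicate 2 they were 434 and 287.

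Beside ZRT1 (log2 change 5.77, SE 0.21, adjusted p = 1.5e-17), the largest rises among the more abundant genes included ZPS1, a gene known as a target of the zinc regulator Zap1. ZPS1 (chromosome XV, 34658 to 35407) rose by 6.18 (SE 0.26, adjusted p = 2.66e-16), from 7.56 ± 0.138 to 554 ± 113 CPM (SD, n = 2). ARG1, for argininosuccinate synthetase (chromosome XV, 219211 to 220473), rose by 5.57 (SE 0.44, adjusted p = 4.71e-10). OPI3, for a phospholipid methyltransferase of phosphatidylcholine synthesis (chromosome X, 572315 to 572935), rose by 3.15 (SE 0.20, adjusted p = 5.58e-12). EHT1, for an ethyl ester synthase, rose by 2.56, ARG56 of arginine synthesis by 2.49, ADH4, an alcohol dehydrogenase gene, by 2.40 and SPT8 of the SAGA coactivator by 2.38.

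The largest falls were led by PHO84 (log2 change -7.83, SE 0.38, adjusted p = 9.48e-15). The acid phosphatase gene PHO12 fell by 3.68, with reads that can belong to its near-identical copy PHO11. VTC3, for a subunit of the vacuolar polyphosphate polymerase, fell by 2.69, and ATG40, for a receptor of endoplasmic reticulum autophagy, by 2.30. COX5B, for a cytochrome c oxidase subunit, fell from 35.3 ± 3.41 to 6.18 ± 2.71 CPM (SD, n = 2). PDR5, for a drug efflux pump, fell from 584 ± 38.7 to 130.2 ± 11.7 CPM (SD, n = 2), a log2 change of -2.17. HXT7, for a high-affinity hexose transporter nearly identical to HXT6, had a log2 change of -2.04. The noncoding gene YNCD0013C had a change of -2.24, with its most used position 127 nt past the annotated end.

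Of 62 amino acid biosynthesis genes tested, 42 rose and 1 fell, and adjusted over the list alone 43 rose and 4 fell. The median log2 change was 0.97 (camera adjusted p = 1.83e-12), with adjusted p = 0.366 with an estimated correlation. ARG3, for ornithine carbamoyltransferase, rose by 3.29, HIS4 of histidine synthesis and TRP4 of tryptophan synthesis each by 2.18, while BAT2, for the cytosolic branched-chain aminotransferase, fell by 1.15. Of 12 phospholipid synthesis genes 7 rose and 0 fell (adjusted over the list alone, 8 and 1), with a median of 0.97 (adjusted p = 0.000992, and adjusted p = 0.366 with an estimated correlation). Beside OPI3, OPI1, the repressor of inositol-regulated genes, rose from 1.31 ± 0.956 to 8.31 ± 0.307 CPM (SD, n = 2). Amino acid and peptide permeases had 8 rises and 1 fall of 19 (the same counts adjusted over the list alone) and a median of 0.47 (adjusted p = 0.0121, and adjusted p = 0.412 with an estimated correlation). PUT4, the proline permease, rose by 1.87 and AGP1, a broad amino acid permease, by 1.77, while PTR2, the peptide transporter, fell by 1.77. Sulfur metabolism had 7 rises and 3 falls of 20 (also adjusted over the list alone), a median of 0.06 and adjusted p = 0.659, with CYS3, for cystathionine gamma-lyase, up by 1.85 and MET14, for adenylylsulfate kinase, at -2.02.

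Purine synthesis had 8 rises and 0 falls of 19, also adjusted over the list alone, with a median of 0.39 (adjusted p = 0.0121, and adjusted p = 0.494 with an estimated correlation). ADE17 of the last purine steps rose by 1.88, ADE3 by 1.47 and SHM2, for serine hydroxymethyltransferase, by 1.26. Pyrimidine synthesis had 5 rises and 0 falls of 8, also adjusted over the list alone, with a median of 0.66 (adjusted p = 0.0121, and adjusted p = 0.366 with an estimated correlation). URA3, for orotidine 5'-phosphate decarboxylase, rose by 1.64 and URA4, for dihydroorotase, by 1.37. Of the 6 tested thiamine and vitamin B6 genes 1 rose and 2 fell, also adjusted over the list alone (median 0.36, adjusted p = 0.898), with PHO3, for a thiamine-repressed acid phosphatase, up by 1.06 and THI6 of thiamine synthesis at -1.48.

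Central carbon genes moved in both directions. Glycolysis and fermentation had 12 rises and 0 falls of 18 (adjusted over the list alone, 14 and 0), with a median of 0.71 (adjusted p = 4.59e-05, and adjusted p = 0.366 with an estimated correlation). ADH1, the main fermentative alcohol dehydrogenase gene, rose by 1.48 and ENO2, for enolase, by 1.43. The TCA cycle list had 9 rises and 1 fall of 22, also adjusted over the list alone, and a median of 0.36 (adjusted p = 0.0121, and adjusted p = 0.366 with an estimated correlation). Within it PYC2, for pyruvate carboxylase, rose by 1.85, and MDH2, for cytosolic malate dehydrogenase, went from 0.249 ± 0.352 to 11.9 ± 2.30 CPM (SD, n = 2). The respiratory chain had 7 rises and 3 falls of 33, also adjusted over the list alone, a median of -0.04 with a mean of 0.03, and adjusted p = 0.814. CYC1, for cytochrome c, rose by 1.73. Among 8 hexose transporters 2 rose and 4 fell, also adjusted over the list alone (median -0.51, adjusted p = 0.507): HXT1, a low-affinity transporter, rose by 1.71 and HXT3 by 0.93, while HXT6 had a change of -2.55.

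Of 13 phosphate response genes tested, 0 rose and 11 fell, also adjusted over the list alone, with a median of -1.71 (adjusted p = 2.31e-08, and adjusted p = 0.366 with an estimated correlation). PHO5, for the repressible acid phosphatase, fell by 3.02, and SPL2 went from 38.2 ± 13.5 to 0.853 ± 1.21 CPM (SD, n = 2). Iron and copper uptake had 1 rise and 8 falls of 16, also adjusted over the list alone, with a median of -0.59 (adjusted p = 0.00757, and adjusted p = 0.481 with an estimated correlation). FRE1, for a ferric and cupric reductase, fell by 1.77 and CCC2, for a copper-transporting ATPase, fell by 1.44, while FTR1, the iron permease, rose by 0.83. Across the 19 lists, 8 were up and 2 were down at the preset correlation of 0.01. With an estimated correlation camera called 0 lists, and 1 had an unadjusted p under 0.05. No other tool was run on the lists.

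Ribosome biogenesis had 26 rises and 2 falls of 86, also adjusted over the list alone, with a median of 0.32 (adjusted p = 0.00441, and adjusted p = 0.366 with an estimated correlation). PWP2 of the small subunit processome rose by 1.58 and LSG1, a GTPase of large subunit maturation, by 1.37. Ribosomal protein genes were split, with 33 rises and 35 falls of 136 (adjusted over the list alone, 35 and 39), a median of 0.06 and adjusted p = 0.907. RPL4A rose by 1.53 and RPL41B had a change of -1.78. Stress genes had 4 rises and 5 falls of 27 (adjusted over the list alone, 5 and 5; median -0.14, adjusted p = 0.585), with the glycogen phosphorylase gene GPH1 at -2.85, GAD1, for glutamate decarboxylase, at -1.58 and the chaperone gene SSE1 at 1.15. Ergosterol synthesis had 6 rises and 2 falls of 23, also adjusted over the list alone (median 0.07, adjusted p = 0.51), and ERG12 and ERG6 rose by 1.08 and 1.04. Cleavage and polyadenylation factors had 4 rises and 3 falls of 21 (adjusted over the list alone, 5 and 3; median 0.07, adjusted p = 0.552). PTA1 of the cleavage and polyadenylation factor rose by 2.34, PAB1, the poly(A)-binding protein gene, by 1.50, and YTH1, for a zinc finger subunit of the same factor, fell by 1.07. RNA polymerase II and termination genes had 4 rises and 2 falls of 22, also adjusted over the list alone (median 0.04, adjusted p = 0.793), with SPT5, for an elongation factor, up by 1.45 and RPB3 by 1.21.

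**Figure D2:**
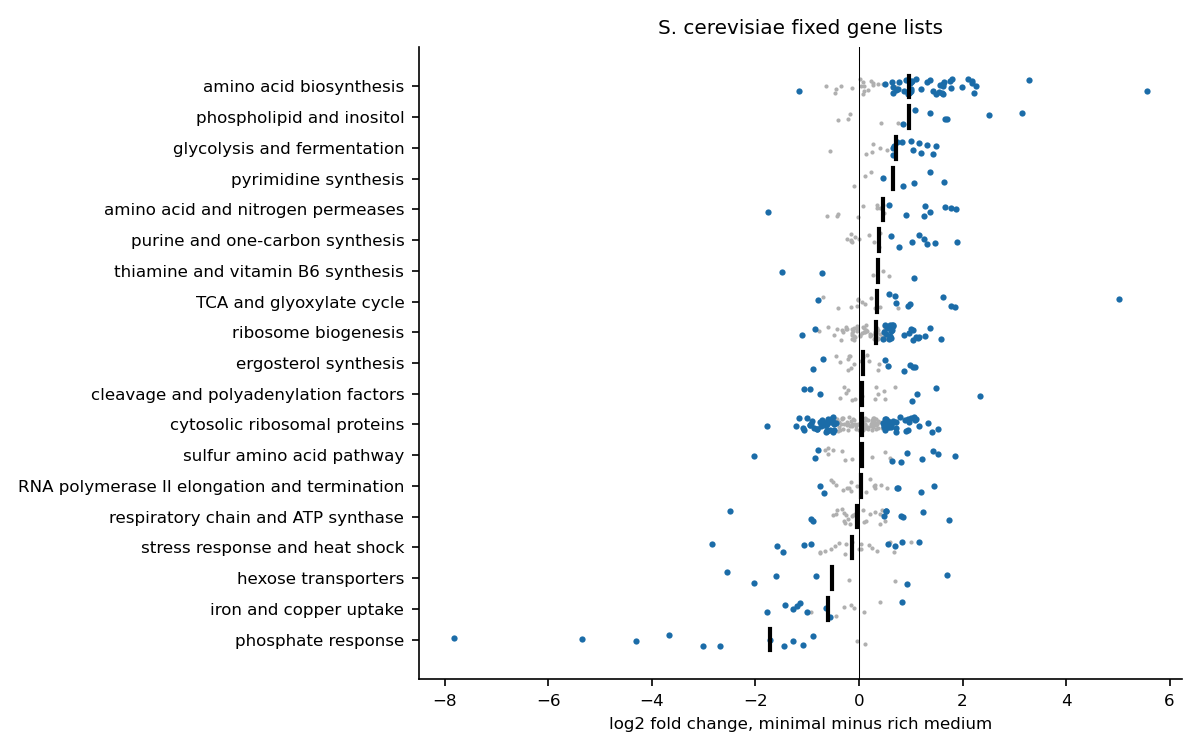
Log2 change of expression, minimal minus rich medium, for the tested members of the 19 S. cerevisiae lists; blue points have an adjusted p under 0.05, grey points do not, and black lines are medians. Amino acid biosynthesis sits highest with phospholipid synthesis (median 0.97 each) and the phosphate response lowest (-1.71).

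Site choice within S. cerevisiae genes was compared between the media. More genes moved toward their distal site in minimal medium than toward their proximal site. ODC2, for a mitochondrial oxodicarboxylate carrier, used its distal site for 39.1% ± 9.19 of reads in rich and 93.1% ± 2.92 in minimal medium (SD, n = 2). Its sites lie at 758346 and 759289 on chromosome XV. SER3, for phosphoglycerate dehydrogenase of serine synthesis, went from 11.2% ± 3.67 to 55.1% ± 2.25 (SD, n = 2), with sites at 322686 and 324289 on chromosome V. In the other direction, NCL1, for a tRNA methyltransferase, went from 92.3% ± 0.781 to 74.0% ± 5.83 (SD, n = 2).

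Of 2460 genes tested, 42 had more distal and 13 more proximal use in minimal medium, and 346 had an unadjusted p under 0.05. These calls rest on every library. edgeR called 0 genes without minimal medium replicate 1 (156 at an unadjusted p under 0.05), 2 and 0 without minimal medium replicate 2, 13 and 5 without rich medium replicate 1, and 3 and 1 without rich medium replicate 2, while DESeq2 called 12 and 3. With sites joined within 12 nt, 9 and 5 genes passed, and 12 of the 55 genes were among them.

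ODC2 had a log2 change of the distal over proximal ratio of 4.34 (SE 0.45, adjusted p = 1.17e-18) and SER3 of 3.22 (SE 0.53, adjusted p = 4.4e-07). The malic enzyme gene MAE1 went from 81.2% ± 8.84 to 100% ± 0 distal reads (SD, n = 2). It had 0 proximal reads in minimal and 8 and 4 in rich medium, so the size of its change is not given. IMD2, for IMP dehydrogenase of GTP synthesis, changed by 4.51, from 82.6% ± 11.6 to 99.3% ± 0.969 (SD, n = 2), and YGR079W by 4.02 (adjusted p = 0.0141). The largest changes toward the proximal site were -3.09 for the importin gene KAP95, -2.08 for PHO3, -2.06 for NCL1, -1.82 for YLR361C-A and -1.73 for TMA46, with BNR1, a formin gene, going from 90.3% ± 3.48 to 70.0% ± 0.921 distal reads (SD, n = 2). SER3 and YGR079W turned to -0.17 and -0.47 with sites joined within 12 nt. In 16 of the 42 genes with more distal use (38.1%) the proximal site lay inside the coding region. Among all 2460 tested genes this held for 297 (12.1%). Against the other tested genes, Fisher's exact test gave an odds ratio of 4.68 (two-sided, p = 1.21e-05). Over all coding genes, start to stop codon held 1.56% and 1.61% of nuclear reads in minimal and 1.89% and 1.99% in rich medium. Of the 13 cleavage and polyadenylation factors tested, 0 passed in edgeR (3 at an unadjusted p under 0.05) and 0 in DESeq2 (0 at an unadjusted p under 0.05). The 3 were NPL3, with the lowest adjusted p (change 0.98, SE 0.45, adjusted p = 0.282), YTH1 (1.70, SE 0.81, adjusted p = 0.314) and RNA14 (-0.52, SE 0.26, adjusted p = 0.329). The other 10, PAB1, RNA15, HRP1, CLP1, SYC1, MPE1, GLC7, SWD2, REF2 and PFS2, lay between -0.55 and 0.74.

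**Figure D3:**
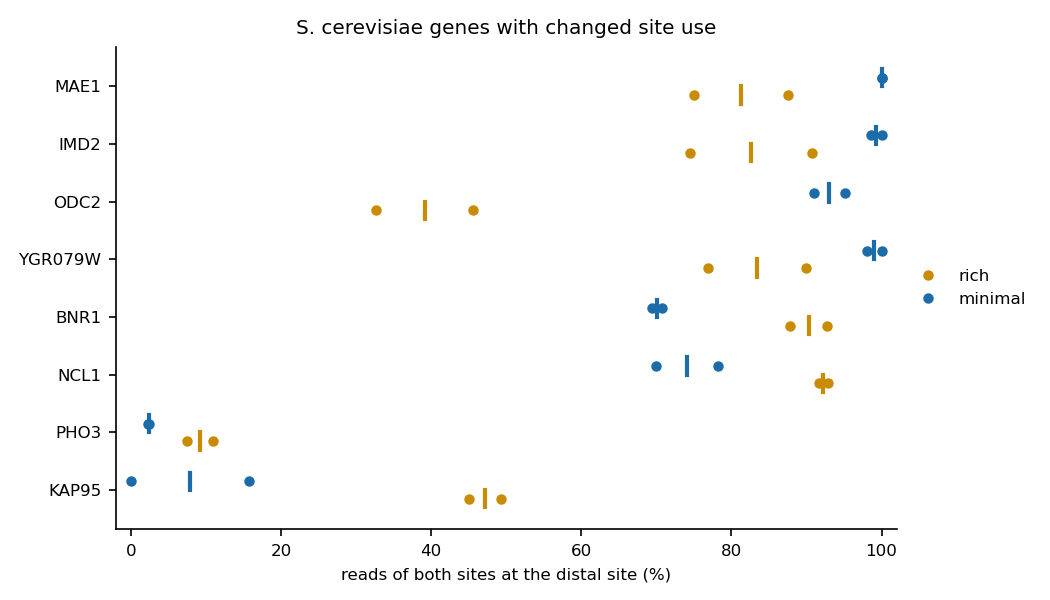
Percent of reads at the distal of each gene's 2 sites, per replicate, in minimal and rich medium, for the 4 S. cerevisiae genes per direction with the largest changes that passed the test; vertical lines are means. ODC2 goes from 39.1% in rich to 93.1% in minimal medium and KAP95 from 47.2% to 7.89%.

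In S. pombe each comparison is between 1 library and another, without replicates, so it compares those libraries and not the conditions. Wild type in minimal against rich medium had 5 of 8 hexose transporter and glucose-repressed genes and 3 of 7 phosphate response genes at least 2-fold higher. adh4, an alcohol dehydrogenase gene on chromosome I (156430 to 157932), had 3254 reads in minimal and 118 in rich medium, a log2 ratio of 5.13 (95% interval 4.87 to 5.42). zrt1, the zinc transporter gene, was higher by 3.25 (3.12 to 3.40), and adh1, the main alcohol dehydrogenase gene, was at -4.64 (-5.41 to -4.08), with 21 and 702 reads. Of 3217 genes, 86 were at least 2-fold higher and 38 at least 2-fold lower. Between S. cerevisiae replicates the same measure gave 1 and 1 of 2189 genes in minimal and 4 and 26 of 2840 in rich medium.

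Further high ratios were those of SPCC794.04C (4.58), the siderophore transporter gene str1 (3.06), SPBPB2B2.06C (2.85) and the hexose transporter gene ght5 (2.84). Low ratios were those of the copper transporter gene ctr4 (-2.89), gdt1 (-2.39), SPAC977.14C (-1.91) and fmd1 (-1.84). Of 8 measured hexose transporters and glucose-repressed genes 5 were 2-fold higher and 0 lower, with a median of 1.28 at percentile 100 of random lists, and inv1, for invertase, was at 2.58. The phosphate response had 3 of 7 higher, a median of 0.69 and percentile 99.9, with tgp1 at 2.47 and the acid phosphatase gene pho1 at 1.59. Respiratory chain and TCA genes had a median of 0.15 over 38 genes (percentile 98.5), with 0 past 2-fold and atp2, an ATP synthase subunit gene, at 0.75. Stress genes had 4 of 25 higher and 1 lower (0.14, percentile 94.7), with ish1 at 1.82 and gst2, for a glutathione transferase, at -1.63. Glycolysis had 2 of 15 higher and 1 lower (0.04, percentile 89.2).

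Ribosomal protein genes had a median of -0.39 over 135 genes (percentile 0 of the random lists), with 2 lower by 2-fold and rpl1902 at -1.12. Ribosome biogenesis was at -0.34 over 55 genes (percentile 0), with 2 lower and utp14 at -1.15. Iron uptake had 1 of 10 higher and 2 lower (-0.45, percentile 0.06). Amino acid synthesis had a median of -0.14 over 54 genes (percentile 4.17), with 4 higher and 2 lower, among them met17, for homocysteine synthase, at 1.82 and sam1, for S-adenosylmethionine synthetase, at 1.53. Purine and one-carbon genes had 3 of 17 higher and 0 lower with a median of -0.21 (percentile 3.85), where gcv2 and gcv1 of the glycine cleavage system were at 2.14 and 2.05. Mating and nitrogen starvation genes had 3 of 11 higher (0.02, percentile 59.5), with the amino acid permease gene isp5 at 1.68. Meiotic mRNAs silenced by Mmi1 had 1 of 4 higher (0.11, percentile 73.1), with mei4, for a meiotic transcription factor, at 1.48, and genes from meiotic screens 0 of 39 (0.05, percentile 70.6). Small nucleolar RNAs had a median of -0.20 over 13 (percentile 5.85) and cleavage factors of 0.07 over 22 (percentile 73.1), with 1 higher, ctf1, at 1.41. The median of 3 thiamine genes was -0.08 (percentile 34.2) and that of 34 polymerase and exosome genes -0.08 (percentile 16.04), and each was 0.01 when scaled by total reads.

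Site use in wild type S. pombe was shifted at least 2-fold to the distal site in 260 and to the proximal site in 118 of 2065 genes, with a median change of 0.21. Replicates of S. cerevisiae gave 57 and 39 of 1250 genes in minimal and 110 and 95 of 1677 in rich medium. rpa49, for an RNA polymerase I subunit, had 97.7% distal reads in minimal (87.9% to 99.6%) and 61.9% in rich medium. SPAC25B8.08 had 91.7% and 59.7%, SPCC569.07 42.3% and 9.57%, and dcr1, the Dicer gene, 6.9% of 29 reads and 0% of 78. More proximal use was seen in nrm1, for a repressor of G1/S transcription, with 46.1% distal reads in minimal and 80.1% in rich medium. SPCC13B11.02C had 25.4% and 66.7%, and tip1, for a microtubule plus-end protein, 1.79% and 20.8%. The distal positions of SPAC25B8.08 and SPCC13B11.02C also lie in noncoding genes of the same strand. Of 18 genes on the list of cleavage and polyadenylation factors 0 were 2-fold more distal and 2 more proximal, pab2 with 36.5% in minimal and 55.6% in rich medium and ctf1 with 5.71% and 11.1%. The other 16 lay between -0.75 and 0.67.

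The PAB2 mutant library was compared with wild type in rich medium. Pab2 is a nuclear poly(A)-binding protein. The pab2 locus had 156 reads in the mutant and 218 in wild type, a log2 ratio of -0.56 (-0.87 to -0.26), and 3' tags check nothing about a mutation of unknown kind. Of the small nucleolar RNAs 15 of 22 were at least 2-fold higher in the mutant, and of the meiotic mRNAs silenced by Mmi1 3 of 6. The 3 include meu1, which was lower within the annotated gene (1 against 19 reads). The lists hold 59 and 18 genes, of which 13 and 4 were measured in the wild-type pair. Some members thus reached the 100-read minimum only through the mutant, so these counts lean upward. snR42 had 1641 reads against 26, a ratio of 5.84 (5.34 to 6.52), and mcp7, a meiotic gene, was at 3.12 (2.72 to 3.60). ecl2, a gene of the lifespan-extending ecl family, was at -4.52 (-4.99 to -4.14), with 50 and 1104 reads. Of 3382 genes, 186 were at least 2-fold higher and 197 lower, and 148 and 269 with scaling by total reads, which shifts all ratios by -0.17. Within the annotated gene alone, 100 were higher and 213 lower of 2816. The reads mark 3' ends, so an end that moves past the annotated gene end leaves that count. Values within the gene can thus fall without fewer transcripts.

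The small nucleolar RNAs had 15 of 22 higher and 3 lower, a median of 2.30 and percentile 100. sno12 was at 5.49, snR92 at 5.32 and SPNCRNA.901, annotated as a small nucleolar RNA, at 4.80. Their main positions lay mostly past the annotated end, 103 nt for snR42 and 78 nt for sno12. Within its annotated bounds sno12 had 7 reads against 0 and snR92 had 1 against 0, as did the tRNA gene SPBTRNAASN.02, which had 122 reads against 1 in its whole region (5.86, interval 4.34 to 12.16), and SPBC23G7.10C was at 5.39. Meiotic mRNAs silenced by Mmi1 had 3 of 6 higher (0.87, percentile 99.9), with mei4 at 1.45. meu1 of that list was at 2.65, with 1 read against 19 within the annotated gene (log2 ratio -3.40, interval of the ratio 0.00120 to 0.313). Genes from meiotic screens had 5 of 47 higher and 0 lower (0.22, percentile 98.7), with meu43 at 4.62 (3.43 to 7.32) from 103 against 3 reads, and at 2.09 within the annotated gene (8 against 1 reads, interval of the ratio 1.01 to 335). Mating and nitrogen starvation genes had 1 higher and 1 lower of 12 (0.12, percentile 69.1, and -0.05 by total reads): rep1, a meiotic transcription activator gene, was at 3.71 and ste4, of the mating kinase cascade, at -1.52.

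Ribosome biogenesis had 6 of 60 higher and 0 lower in the PAB2 mutant (0.48, percentile 100), with imp4 at 2.13 and the RNA helicase gene dbp2 at 1.82. Ribosomal protein genes were at 0.13 over 137 (percentile 86.2, and -0.04 by total reads), with 1 higher, rpl3002, at 1.95. Glycolysis was at 0.34 over 15 genes (percentile 98.6) and the phosphate response at 0.73 over 7 (percentile 99.5), where 1 was higher and 2 were lower, among them vtc4 at -1.95. Hexose transporters and glucose-repressed genes had a median of -0.92 over 5 (percentile 0.2), with gut2, for glycerol-3-phosphate dehydrogenase, at -2.54. Purine genes were at -0.39 over 17 (percentile 0.15), with ade5 at -3.53, and respiratory genes at -0.11 over 38 (percentile 4.19), with 2 higher and 3 lower. cox13, of cytochrome c oxidase, was at 1.58 but -0.23 within the annotated gene. Stress genes had 0 higher and 5 lower of 29 (0.06, percentile 59.8, and -0.11 by total reads), with the small heat shock gene hsp16 at -4.23 and the phosphatase gene pyp2 at -1.72. Iron uptake had 1 higher and 2 lower of 9 (-0.02, percentile 42.5), with sib2, of siderophore synthesis, at -3.56 and str1 at 1.55.

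Amino acid synthesis was at -0.01 over 55 genes (percentile 18.5), with 1 higher, his5, at 1.69, whose main position lay 395 nt past the annotated end and which was at 0.16 within the annotated gene. The 3 thiamine genes were at 0.16 (percentile 61.2, and -0.01 by total reads), the 21 cleavage factors at 0.11 (percentile 69.3, and -0.06 by total reads), and the 34 polymerase and exosome genes at 0.18 (percentile 93.7), where erh1, for the partner of Mmi1, was at -2.13. The lowest ratio of all was that of ecl3, at -5.40 (-8.10 to -4.24) from 3 against 159 reads. SPCC63.13 was at -5.08, SPAC343.21 at -4.70 and tcd1 at -4.22. SPAC343.21 was at -2.20 within the annotated gene (2 against 12 reads, interval of the ratio 0.0171 to 0.707).

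Distal sites were used more in the PAB2 mutant library: 756 of 2223 genes were at least 2-fold more distal and 97 more proximal, with a median of 0.52. Start to stop codon held 0.717% of its nuclear reads, against 1.82% in wild type. The proximal site lay inside the coding region in 147 of the 756 genes (19.4%), 23 of the 97 (23.7%) and 235 of all 2223 (10.6%). With both sites downstream of the stop codon, 609 of 1988 genes were more distal and 74 more proximal. pho84, for a phosphate transporter, had 76.2% distal reads (74.2% to 78.0%) against 1.20% in wild type (0.748% to 1.91%). fhn1, for an eisosome protein, had 91.7% (89.5% to 93.5%) against 10.1% (9.04% to 11.2%). atd1, for an aldehyde dehydrogenase, had 99.7% against 75.6%, cao2, for a copper amine oxidase, 91.7% of 12 reads against 0.962%, SPACUNK4.15 99.2% against 16.7%, and thi20 of thiamine synthesis 100% against 30.2%. The distal positions of pho84, fhn1 and cao2 also lie in the same-strand noncoding genes nc-pho1, SPNCRNA.133 and SPNCRNA.6608, so the transcript their reads come from is not settled. In all, 27 of the 756 genes had the distal position in another gene of the same strand. With sites joined within 12 nt SPACUNK4.15 turned to -4.68. More proximal were pan5 at 41.5% against 98.2%, sua7, for the general transcription factor TFIIB, at 8.22% against 71.4%, tts1 at 42.5% against 93.2% and mcp7 at 0% of 428 reads against 18.4% of 38. Of 17 genes on the list of cleavage and polyadenylation factors 7 were 2-fold more distal and 0 more proximal. The 7 were cph2 (93.0% against 41.3%), pab2 (87.0% against 55.6%), hrp1 (18.7% against 3.74%), rna14 (3.54% against 0.697%), swd22 (52.7% against 24.7%), yth1 (46.3% against 23.6%) and pabp, for the cytoplasmic poly(A)-binding protein (82.7% against 70.3%). The distal position of hrp1 also lies in the same-strand noncoding gene SPNCRNA.804. The other 10, cft1, cph1, pab1, for a protein phosphatase 2A subunit, ssu72, cft2, pla1, dis2, iss1, msi2 and seb1, lay between -0.65 and 0.89, and with sites joined within 12 nt rna14 turned to -0.47.

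The PCF11 mutant library was compared with wild type in minimal medium. Pcf11 is a subunit of the cleavage machinery that also acts in transcription termination. The pcf11 locus had 204 reads against 92, a log2 ratio of 1.63 (1.28 to 2.01), which again says nothing of an unknown mutation. The distal site of most genes with 2 sites was used more: 969 of 1751 were at least 2-fold more distal and 192 more proximal, with a median change of 1.22. wos2, for a co-chaperone, had 99.8% distal reads (99.7% to 99.9%) against 5.62% (3.96% to 7.91%), a log2 change of 13.02. Of 22 small nucleolar RNAs measured, of 59 on the list, 18 were at least 2-fold higher and 2 lower. In the wild-type pair 13 were measured, so some entered only through the mutant reads and these counts lean upward. The U1 small nuclear RNA gene snu1 had 5229 reads against 69.

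The same direction was seen in yhm2, a mitochondrial carrier gene, with 100% against 20%, in scr1, for a glucose repressor, with 98.6% against 0.758%, and in pre8, for a proteasome subunit, with 79.0% against 0%. tht2 had 100% against 0% of 8 reads and sdh8 98.6% against 0%. Of the 969 genes, 39 had the distal position in another gene of the same strand, among them pre8, whose position lies in SPNCRNA.7495, and hrp1, whose position lies in SPNCRNA.804. More proximal were bip1, for the endoplasmic reticulum chaperone, at 36.0% against 99.6%, mns1 at 4.23% against 100%, erg27 at 37.6% against 100%, icp55 at 36.4% against 98.7%, rpb11, for an RNA polymerase II subunit, at 10.9% against 95.9%, and eaf7 at 7.22% against 100% of 9 reads. On the list of cleavage and polyadenylation factors 12 of 17 genes were at least 2-fold more distal and 1 more proximal: pcf11 had 99.4% against 22.9%, rna14 43.5% against 0.82%, cft1 65.4% against 2.52%, pabp 98.3% against 62.2% and pab2 100% against 36.5%. hrp1 had 71.0% against 5.71%, swd22 80.5% against 27.9%, ctf1 47.6% against 5.71%, ssu72 95.3% against 63.2%, msi2 91.7% of 12 reads against 53.1%, yth1 60% against 30.4% and pab1, the phosphatase subunit gene, 89.2% against 76.6%. The more proximal gene was iss1, with 9.34% against 29.9%, and pla1, seb1, cft2 and dis2 lay between -0.89 and 0.38. With sites joined within 12 nt cft1 turned to -0.31, and within 48 nt msi2 turned to -0.18.

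Gene reads also differed widely in the PCF11 pair. Of 2925 genes, 689 were at least 2-fold higher and 736 lower, and 394 and 1280 with scaling by total reads, which shifts all ratios by -0.67. Within the annotated gene, 388 were higher and 769 lower of 2299, with a median of -0.43. Ends moved past the annotated gene end lower these values too. fub2 had 279 reads against 0, a log2 ratio of at least 7.03 over the 3-count floor. hut1 was at 7.50 (6.97 to 8.22), SPAP27G11.11C at 7.19 (5.90 to 10.82) from 310 against 2 reads, and mde2, a meiotic gene, at 6.75 (5.24 to 13.05) from 152 against 1. The main positions of fub2 and hut1 lay 82 and 60 nt past the annotated end. hut1 was at 0.84 within the annotated gene (13 against 10 reads), and mde2 had 1 read against 0. tcd1 was at -4.33, ecl2 at -4.27, SPCC63.13 at -4.05, oms1 and rrp17 each at -3.94 and ftp105 at -3.89.

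The small nucleolar RNAs had a median of 2.82 (percentile 100) and 2 lower, with sno12 at 7.07, from a region with 2 reads against 0 inside the gene, and snR93 at 5.69. Meiotic mRNAs silenced by Mmi1 had 5 of 7 measured genes higher and 1 lower, of 18 on the list (2.46, percentile 99.97). Among them jnm1 was at 6.49 and crs1, a meiotic cyclin gene, at 4.41, or 2.14 within the annotated gene (24 against 7 reads). Genes from meiotic screens had 20 of 39 higher and 10 lower (1.02, percentile 99.99), with mug68 at 6.37, and mating genes 6 of 12 higher and 2 lower (0.99, percentile 99.1), with isp6 at 1.56. Ribosome biogenesis had 29 of 55 higher and 4 lower (1.12, percentile 100, and 0.46 by total reads), with utp4 at 2.89 and rlp7 at 2.82. Ribosomal protein genes had 15 higher and 16 lower of 136 (-0.13, percentile 1.38), with rps601 at -2.73 and rpl1102 at 3.18, which was -0.22 within the annotated gene. Glycolysis had 7 of 15 higher and 1 lower (0.71, percentile 86.9, and 0.04 by total reads), with adh1 at 4.67 and tdh1 at 3.64. Respiratory genes had 8 higher and 6 lower of 37 (0.36, percentile 87.5, and -0.31 by total reads): sdh1, of succinate dehydrogenase, was at 4.87, with its main position 216 nt past the annotated end and 0.92 within the annotated gene (34 against 25 reads), and cit1, for citrate synthase, was at -2.99.

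Cleavage factors in the PCF11 pair had 8 higher and 5 lower of 21 (0.33, percentile 78.9, and -0.33 by total reads), with pabp at 3.57 and dbp2 at 2.75. Polymerase and exosome genes had 3 higher and 7 lower of 25 (-0.15, percentile 42.0), with the nuclear exosome gene rrp6 at 3.65 and erh1 at -2.64. Purine genes had 2 higher and 7 lower of 17 (-0.86, percentile 1.77), with ade7 at -3.36, and amino acid genes 5 higher and 11 lower of 52 (-0.17, percentile 24.9), with gdh1, for glutamate dehydrogenase, at 2.73 but -0.13 within the annotated gene. Iron uptake had 0 higher and 3 lower of 5 (-1.22, percentile 7.09), phosphate response genes 0 and 2 of 6 (-0.71, percentile 12.8) and hexose transporters 0 and 3 of 8 (-0.69, percentile 17.5), with ght5 at -2.24. Stress genes had 4 higher and 4 lower of 21 (0.10, percentile 58.6, and -0.56 by total reads). Of 4 thiamine genes 1 was higher, thi9, with 7 against 7 reads within the annotated gene, and the median was -0.11 (percentile 50.4).

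**Figure D4:**
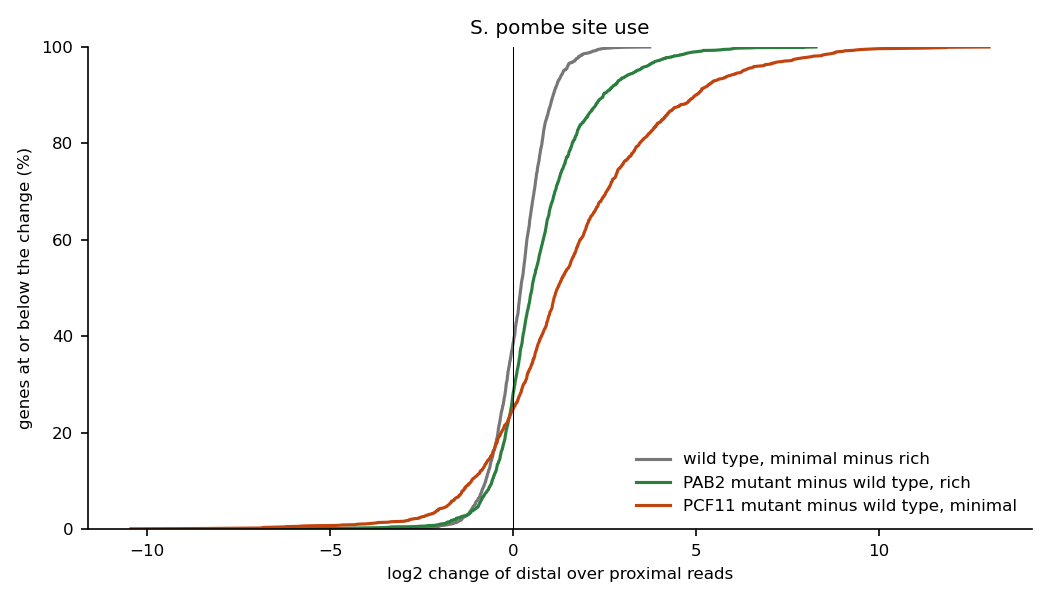
Cumulative percent of S. pombe genes by log2 change of the distal over proximal ratio for the medium, PAB2 mutant and PCF11 mutant comparisons, each of 1 library against another. The medians are 0.21, 0.52 and 1.22.

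The mutant comparisons share no library, since one pair was grown in rich and the other in minimal medium. They do share the sites, which were ranked over all 4 S. pombe libraries. Sites used mainly in the mutants could be picked for that reason, so part of the overlap in site use may be built in. The site use changes of both comparisons correlated across 1646 genes at Pearson r = 0.493 and Spearman rho = 0.540. Genes are not independent replicates, so no p is given. At least 2-fold more distal use in both was found in 454 genes, against 302.0 for independent changes, and more proximal use in both in 23 genes, against 5.69. In expression, of 2795 genes, 107 were at least 2-fold higher in both (30.03 for independent changes) and 110 lower in both (38.8). At 4-fold, 33 were higher in both (3.07) and 17 lower (2.14). The 17 included the lifespan gene ecl2 at -4.52 and -4.27, wsp1, for a regulator of actin assembly, at -3.91 and -2.58, the purine synthesis gene ade5 at -3.53 and -2.06, and the autophagy genes atg101 and atg7. Within the annotated gene 14 of the 17 were still 4-fold lower in both. There sts5 was at -2.02 (5 against 22 reads) and -0.51 (7 against 15 reads), and atg101 and erh1 had 0 to 8 reads per library of these pairs, too few to compare. Site use and expression changes correlated across genes at rho = 0.33 in the PCF11 pair and -0.04 in the PAB2 pair. Between media, rho was -0.11 in S. pombe and -0.01 in S. cerevisiae. Both measures share reads, since reads at either site, also past the gene end, count as expression of the gene. These rho values therefore cannot tell a link between site choice and expression from that overlap.

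**Figure D5:**
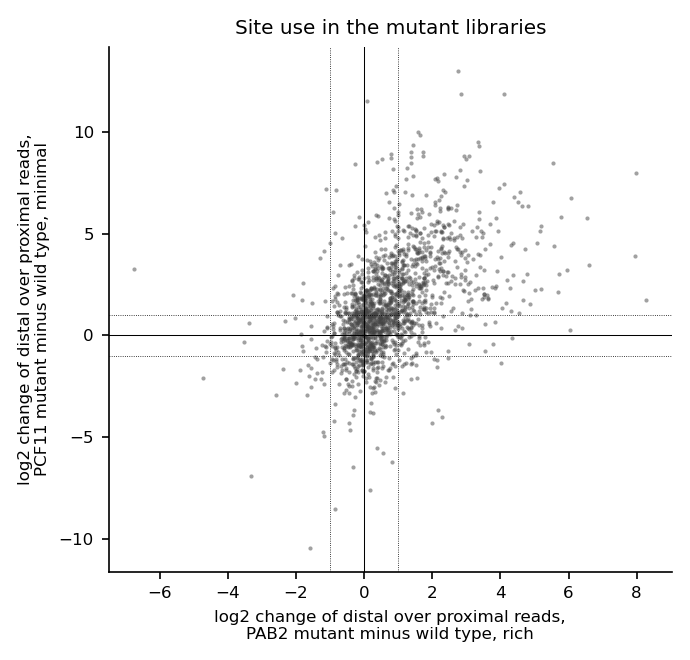
Log2 change of the distal over proximal ratio in the PAB2 mutant pair against that in the PCF11 mutant pair, 1 point per S. pombe gene, 1646 genes, with dotted lines at 2-fold. The points lean to the upper right, with r = 0.493 across genes and 454 genes past 2-fold in both.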

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

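Tests chosen only after the result was seen were those of unequal read numbers, of other transcripts past the gene end, and of a lost locus; the values within annotated genes were also added then.

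Reads on sequences other than the chromosomes were not part of any comparison. Those on MT, the mitochondrial genome, were 2.67-fold as frequent in the PCF11 mutant library as in its wild type (27 against 8 reads, interval 1.18 to 6.80), and those on MTR, the mating type region, 3.30-fold (75 against 18 reads, interval 1.95 to 5.86). In the PAB2 pair the ratios were 1.76 for MT (13 against 6 reads, 0.624 to 5.65) and 0.0542 for MTR (1 against 15 reads, 0.00129 to 0.352). On a further sequence placed on no chromosome, reads were 0.158-fold as frequent in the PCF11 mutant library (823 against 4126 reads, 0.146 to 0.170) and 0.332-fold in the PAB2 mutant library (1657 against 4060 reads, 0.313 to 0.351). From rich to minimal medium, the median of the ribosome biogenesis genes was -0.34 in S. pombe and 0.32 in S. cerevisiae. The median of the phosphate response genes was 0.69 in S. pombe and -1.71 in S. cerevisiae. These differences between species were not tested, and the S. pombe values come from 1 library per medium.

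The PCF11 mutant library used distal sites more in 969 of 1751 genes. The sites were ranked with the mutant libraries included, which may raise this count, and no ranking on wild type alone was made. Unequal read numbers are argued against, since after thinning to equal reads 57.3% of 1591 genes were still at least 2-fold more distal. Reads of other transcripts starting past the gene end are argued against as the whole source, since the share was 50.8% of 1139 genes with the distal site inside the annotated transcript, and 50.5% of the 1124 of them whose distal site lay in no other gene of the same strand. A consequence of the mutation may fit both values, but it was not tested, and the culture or library may differ in other ways with 1 library per group.

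In both mutant libraries 17 genes were at least 4-fold lower than in wild type, SPCC63.13, ecl2, tcd1, wsp1, ade5, pfl2, sts5, gyp10, atg101, ftp105, dop1, adg3, SPAC26H5.09C, cao2, gal10, erh1 and atg7. Transcripts ending within 1000 nt past the gene end and before the next same-strand gene are argued against for this set. With genes extended by 1000 nt, 100% of the 17 stayed 4-fold lower. Reads from a downstream gene's start codon on were counted to that gene, so ends within or beyond it stay open. Of the 17, 14 had more than 3 reads within the annotated gene in both mutant libraries. Loss of the locus is argued against where such reads were many, as in gyp10 (203 in the PAB2 and 113 in the PCF11 mutant), dop1 (90 and 55), atg7 (72 and 51) and ade5 (66 and 84). SPCC63.13 had 4 and 5, sts5 5 and 7 and tcd1 17 and 6. Stray reads could give so few, so loss is not decided where reads were few. With reads past the gene end counted, 100% of the 17 had more than 3 reads in both mutant libraries. Such reads can be of other transcripts, so loss also stays open for atg101, erh1 and cao2. Within the annotated gene 14 of the 17 were still 4-fold lower in both. There sts5 was at -2.02 (5 against 22 reads) in the PAB2 pair and -0.51 (7 against 15 reads) in the PCF11 pair, so its 4-fold call in the latter rests on reads past the gene end. atg101 and erh1 had 0 to 8 reads per library of these pairs, too few to compare. A strain background shared by the mutants, or an effect common to both mutations, stays open and untested.

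The 16 S. cerevisiae genes with a coding-region proximal site and more distal use in minimal medium included ODC2, YGP1, DBP2, SER3, DEF1, MAE1, IMD2, CDC39, HSL7, FCY2, YGR079W, BUD21, MDE1, HOG1 and LYS9. Priming on A stretches stays open. The median number of A in the 10 nt after the site differed by 0 from other coding-region proximal sites (3 and 3). At the most used S. cerevisiae sites past the stop codon, the position itself was A in 90.7% and the next base in 0%. A stretch that primed could thus lie at or before the position, where A was not counted, so the test cannot decide. For a constant level of coding-region reads under a rising full-length transcript, the proximal CPM was examined. It had a median log2 change of -1.33 and was lower in 16 of 16 genes. These genes were picked by a higher distal over proximal ratio in the same reads. The fall is therefore partly built in and cannot decide the question. Reads from the end of an upstream neighbour cannot be told apart for these genes, since 18.8% of the 16, BUD21, MDE1 and HOG1, had a same-strand gene ending 1 to 500 nt upstream, between the bounds set in advance, against 21.4% of 281 others (Fisher's exact test, p = 1). The effect of the medium on the genes stays open.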

How the results depend on the processing

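Of the alternatives, those added after seeing the data were the reads within the annotated gene, the 1 to 500 nt region, and the single libraries left out for the end position. Over the 25 results that answer a comparison, 97 alternative values stayed within the bound set for them and 67 moved. Over 298 single genes and lists, 1438 stayed, 211 moved, 71 lost their call and 12 reversed. The cause of each was not tested, except where fewer genes or libraries entered by construction. Depth limits the S. pombe counts, which rise and fall with the minimum reads. Where a library was left out, the lone library of its medium was assumed to vary like the others.

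S. cerevisiae expression gave 484 rises and 360 falls with DESeq2, and 408 to 974 rises and 277 to 917 falls without 1 library. Of the 1547 calls, 843 were shared by DESeq2 and 659 to 1409 without 1 library, none in the opposite direction. Site use gave 12 genes more distal and 3 more proximal with DESeq2, 9 and 5 with sites joined within 12 nt, 24 and 7 within 48 nt (of the 55 calls 47 were tested, 20 called again in the same direction and 1 in the opposite direction), 17 and 6 with at least 50 reads, and 22 and 12 with both sites downstream of the stop codon. Without 1 library it gave 0 to 13 and 0 to 5. Lists called with an estimated correlation were 0 up and 0 down (camera, 1 at an unadjusted p under 0.05). The end position difference was 5.10 nt with all reads of the gene and 0.875 to 1.92 nt without 1 library. With the replicate number as a replicate block, 902 genes rose and 806 fell and 54 and 19 passed for site use, although the numbers only share a label: replicate differences correlated at 0.0630 between the media.

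S. pombe medium expression gave 141 higher and 86 lower with at least 30 reads, 44 and 19 with at least 300, and 14 and 3 at 4-fold. Its site use gave 556 more distal and 277 more proximal with at least 30 reads, 96 and 38 with at least 300, and 64 more proximal with a pseudocount of 5. The PAB2 pair gave 285 higher and 380 lower with at least 30 reads, 98 and 73 with at least 300, 56 and 44 at 4-fold, and 100 higher within the annotated gene. Its site use gave 1293 and 198 with at least 30 reads and 313 and 22 with at least 300. The PCF11 pair gave 394 higher and 1280 lower with total reads, 1126 lower with at least 30 reads, 384 and 353 with at least 300, 304 and 200 at 4-fold, and 388 higher within the annotated gene. Its site use gave 1597 and 388 with at least 30 reads and 439 and 79 with at least 300.

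For genes with several sites, the distance from the highest S. cerevisiae to the lowest S. pombe wild-type library was 3.41 points with sites joined within 12 nt, 17.6 within 48 nt, 6.50 with 20 reads per gene and 5.94 for 1 to 500 nt. With 20 reads per gene, a single read counts as a site. With the most used site of each gene alone, 67.6% of S. cerevisiae sites had TAYRTA and 17.7% of S. pombe sites AATAAA, against 56.5% and 13.5% over all sites. The mutants correlated at 0.546 with at least 300 reads. Reversed values with sites joined within 12 nt were -0.47 for YGR079W, -0.17 for SER3, -4.68 for SPACUNK4.15, -0.47 for rna14 in the PAB2 pair and -0.31 for cft1 in the PCF11 pair. Within 48 nt, msi2 was at -0.18. Within the annotated gene, cox13 was at -0.23, meu1 at -3.40 (1 against 19 reads), gdh1 at -0.13, rpl1102 at -0.22 and erh1 in the PCF11 pair at 2.66 (8 against 1 reads, too few to compare). Moved below 2-fold there were hut1 at 0.84, sdh1 at 0.92 in the PCF11 pair and 0.10 in the PAB2 pair, his5 at 0.16, thi9 at 0.49, and snR92 and SPBTRNAASN.02 at 0.92 (1 read against 0 each). crs1 moved to 2.14, meu43 to 2.09 and SPAC343.21 to -2.20. With genes extended by 250 nt, meu1 was at -3.38.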

Other observations

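The test of the distance from the start codon was chosen only after the result was seen.

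A hypothesis for the 16 S. cerevisiae genes with a coding-region proximal site and more distal use in minimal medium is that the proximal reads may come from transcripts that start upstream of the gene and end near its start codon. SER3 and IMD2 are textbook cases of genes with such upstream transcription. If so, the proximal sites should crowd near the start codon. Of the 16 sites, 11 (68.8%) lay within 100 nt of it, against 82 of 281 other coding-region proximal sites (29.2%; Fisher's exact test, two-sided, odds ratio 5.34, p = 0.00176). Distances included 0 nt in SER3 and MDE1, 4 nt in HSL7, 6 nt in MAE1, 16 nt in ODC2, 20 nt in YGP1, 23 nt in LYS9, 25 nt in IMD2 and BUD21, and 27 nt in HOG1. Counting began at the start codon, so sites at 0 nt may extend upstream of it. Where transcription starts was not measured, and the test was run on the data in which the pattern was seen.

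Another hypothesis is that the minimal medium may hold less available zinc, since ZRT1, ZPS1 and ADH4 rose in S. cerevisiae. The prediction was made on a list of 8 other genes known as targets of the zinc regulator Zap1. Of these, 3 rose (37.5%), ZRT3 by 1.67, ZAP1 by 2.03 and VEL1 by 2.12, and 2 fell, DPP1 with -0.99 and IZH2 with -0.78, while 17.6% of all tested genes rose. FET4 at -0.16, ZRC1 at 0.44 and IZH1 at 0.59 did not pass. The share lay between the bounds set for and against the hypothesis, so it stays undecided. ADH1 rose by 1.48 in S. cerevisiae, whereas in S. pombe adh1 was lower (-4.64) and zrt1 and adh4 were higher (3.25 and 5.13) in minimal medium.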
